A study of Rattus norvegicus with 9 samples.

How the data were processed

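The series holds RNA-seq of rat horizontal basal cells (strain SD, primary culture at passage 7), with 3 libraries of vehicle-treated cells (0.1% DMSO, labelled time 0), 3 of cells after 6 h in 50 nM PMA and 3 after 12 h. The submitters extracted RNA with a column kit and DNase, and a company prepared the libraries. Group and replicate number were read from the sample titles and checked against the treatment and time labels. The labels do not tie the replicate numbers to animals, culture batches or days.

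As deposited, each library has a table of counts, which per the labels the authors made by aligning reads to the rn6 genome with STAR 2.7.5b, with 1 unstranded column and 1 column per strand. The gene annotation behind the tables is not given in the sources used here. A further deposited table holds a normalized signal per gene and library, which per the labels comes from DESeq2 (no version stated). Tested on the values, the deposited signal was the unstranded count divided by 1 factor per library for 100% of nonzero values (relative tolerance 1e-04, 17289 genes compared), with factors from 0.713 to 1.44. The unstranded column was used for every comparison, and the columns per strand held 49.8% to 50.3% of the summed strand counts each. Reads that fell on overlapping genes or mapped to several places were counted apart from the genes. Overlapping antisense partners, which this column does not part by strand, and near-identical gene copies can therefore lose reads. Each table held 17315 genes, and its 4 summary lines were kept out. In the deposited normalized values 26 gene symbols had been turned into dates, and these 26 lines were left out of the comparison of both tables. Against the symbol table of a newer rat assembly, 14810 symbols were current, 2114 were synonyms and 391 matched nothing. That table served only for names and for which genes neighbour each other.

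Libraries held 13601635 to 19001819 reads in genes, which were 67.8% to 71.3% of all reads. Unmapped reads made up 3.88% to 7.61%, multimapping reads 5.95% to 7.74%, reads outside annotated exons 16.6% to 18.6% and ambiguous reads 0.526% to 0.740%, and 11071 to 11483 genes had a read. Counting error alone would give a ratio of 1 for the chi-square per degree of freedom between replicates, which was 3.94 to 28.9, so no libraries were copies of each other. The floor for a gene without a read was set at 3 counts over the group. Ratios with 1 to 3 reads in a group carry 95% exact (Clopper-Pearson) counting intervals.

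Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr at its minimum count of 10, which left 10128, and library totals were scaled by TMM. Levels are CPM of the scaled totals. A quasi-likelihood model with robust dispersions was fitted to all 9 libraries with group as its only term, and 6 h against vehicle, 12 h against vehicle, 12 h against 6 h and all 3 groups were tested by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the 10128 genes, at adjusted p under 0.05. The common dispersion was 0.0125, a coefficient of variation of 11.2%. Temporal classes combined the calls of the 3 pairwise tests: transient (called at 6 h, then called the opposite way from 6 h to 12 h), progressive (called the same way in both steps), sustained (called the same way at 6 h and 12 h, no call between them) and late (no call at 6 h, called the same way at 12 h against vehicle and against 6 h).

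The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The lists held 526 entries: basal cell identity, hemidesmosome and basement membrane, p63-activated genes, immediate early and AP-1, ERK feedback, EGF family, PKC and PKD, NF-kB and inflammatory, matrix proteases and plasminogen, wound-activated and squamous, Notch pathway, Wnt pathway, TGF-beta and BMP, YAP and TEAD targets, DNA replication and S phase, G2 and mitosis, CDK inhibitors and growth arrest, mesenchymal transition and junctions, chromatin modifiers, cholesterol synthesis, interferon response, NRF2 and oxidative stress, unfolded protein and heat shock, and glycolysis and hypoxia. Markers of other cell types the cultures might hold formed the lists neuronal lineage, sustentacular and gland, respiratory and microvillar, fibroblast and pericyte, immune, and endothelial and glial. Some genes stand in more than 1 list, such as Krt5, Krt14, Itga6, Itgb4, Col17a1, Egfr, Notch1 and Bmp7, but no gene of the other cell types does. Each list with at least 2 measured genes was tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 29 lists and 3 comparisons (87 tests). In 28 tests, of 15 lists, the adjusted p was under 0.05, and in 0 with a correlation estimated from the data. With that estimated correlation 11 camera tests had an unadjusted p under 0.05. The rotation test fry of limma gave 76, and it asks whether list members shifted in 1 direction, without regard to other genes. List members were also counted as rising or falling by edgeR's test, adjusted over all genes and adjusted over the list alone. The text names, per comparison, up to 6 genes with the largest rise and up to 6 with the largest fall among called genes with a mean of at least 5 CPM and groups that do not overlap (clone-like symbols excluded), 8 panel genes (Tp63, Krt5, Krt14, Icam1, Sox2, Hbegf, Fosl1 and Myc), up to 4 called members per list by size of change, and 4 genes per temporal class. Members that did not pass or went against their list were named after their values were seen.

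The model was tested on simulated data at the observed depth and spread. In simulations of 9 libraries and 10128 genes, changes were planted in the 3 libraries at 6 h. They came to 201 1.5-fold, 201 2-fold and 198 4-fold changes, summed over the simulations. From these edgeR recovered 53.2%, 84.1% and 96.5%, and 5.46% of its calls were false. In the data 76.8% of genes were called at 6 h, so recovery and false share need not be the same there. Recovery was also counted by level and at 0.5 of the depth. In 20 simulations of 9 libraries with no effect edgeR called 0.3 genes at 6 h, 0.45 at 12 h, 0.15 between the times and 0.75 over the 3 groups on average. Alternatives were run for scaling (RLE, upper quartile, none), the filter on low counts (none beyond 1 read, or a CPM of 1 in 3 libraries), the tool (DESeq2, limma-voom, limma-trend on the log2 of the deposited values), the count column, the replicate number as a block, only the 6 libraries compared, a fold change of at least 2, and each library left out in turn. Checked with other splits of the libraries, results were recounted over all 10 splits for pairs of groups and over 100 drawn splits for 3 groups.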

Results

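RNA was sequenced from cultured rat horizontal basal cells, the reserve stem cells of the olfactory epithelium, at passage 7. The cultures received vehicle (0.1% DMSO, labelled time 0) or 50 nM phorbol 12-myristate 13-acetate (PMA), an activator of protein kinase C, for 6 h or 12 h, and each of these 3 groups held 3 libraries. Reads assigned to genes came to 14626173 to 18118499 per vehicle library, 15489394 to 19001819 after 6 h and 13601635 to 16912465 after 12 h. No vehicle libraries were labelled with 6 h or 12 h, so no comparison separates PMA from time in culture. Levels are given as means ± SD (n = 3) in CPM, the count of a gene relative to its scaled library total, and log2 fold changes with their SE. A gene without a read in a group had at most 0.0460 CPM in vehicle, 0.0661 CPM at 6 h or 0.0750 CPM at 12 h, from a floor of 3 counts over the group. Intervals and floors cover counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries.

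The series is described as following horizontal basal cells through stages of activation, and the first comparison asks what had changed after 6 h of PMA. The keratins that mark basal cells dropped steeply. Krt5 fell from 6827 ± 817 to 402 ± 51.6 CPM (log2 fold change -4.08 ± 0.16, adjusted p = 1.1e-10), and its partner Krt14 fell from 5325 ± 269 to 779 ± 85.3 CPM (-2.77 ± 0.10, adjusted p = 7.6e-14). Tp63, the transcription factor that holds horizontal basal cells in their resting state, fell from 219 ± 26.6 to 47.9 ± 3.18 CPM (-2.19 ± 0.09, adjusted p = 7.7e-13). Sox2, a transcription factor of olfactory progenitors, fell from 2.93 ± 0.467 to 0.716 ± 0.472 CPM (-2.06 ± 0.42, adjusted p = 2.8e-04; -2.70 without PMA 6 h replicate 2). Hbegf, a ligand of the EGF receptor, rose from 233 ± 8.82 to 1886 ± 86.8 CPM (3.02 ± 0.08, adjusted p = 1.1e-15). Fosl1, an AP-1 subunit, rose from 234 ± 29.3 to 579 ± 26 CPM (1.31 ± 0.08, adjusted p = 2.0e-10), and Myc rose from 180 ± 10.9 to 311 ± 8.57 CPM (0.79 ± 0.07, adjusted p = 1.4e-08). Icam1, a surface protein of horizontal basal cells, rose from 143 ± 11.2 to 176 ± 18.7 CPM (0.30 ± 0.10, adjusted p = 0.0085). That call was lost without PMA 6 h replicate 2 (0.23), and the sign turned without normalization (-0.24).

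**Figure D1:**
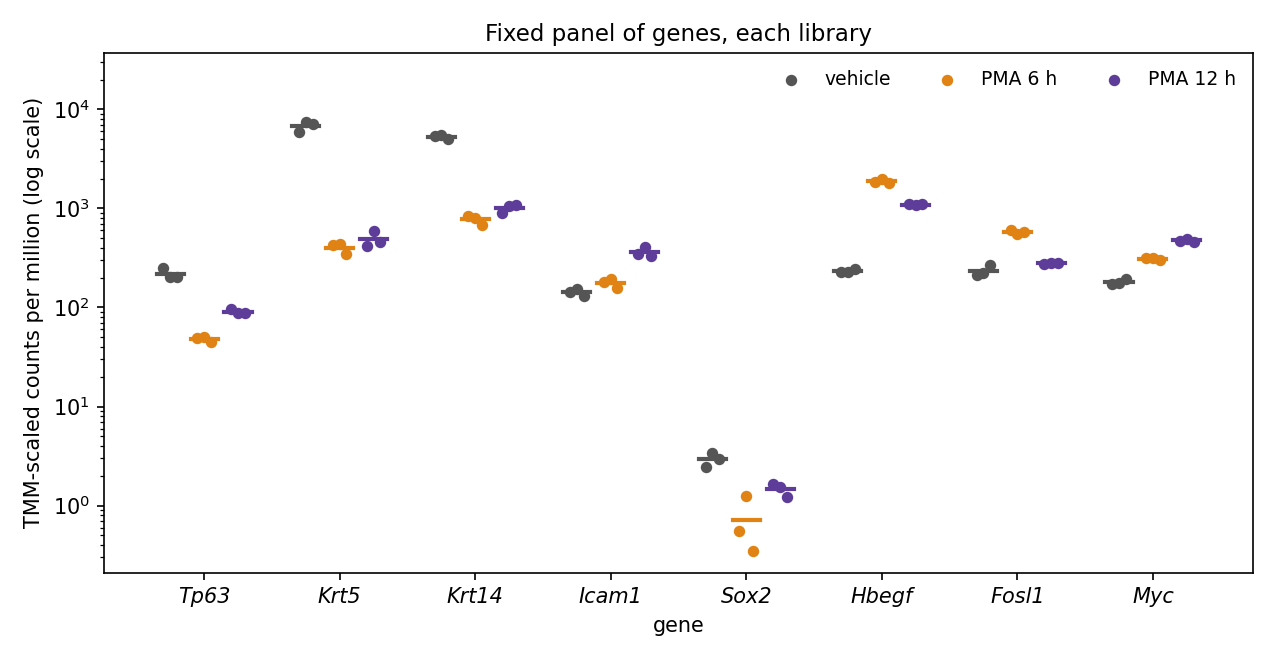
Level of the 8 panel genes in each library, in TMM-scaled CPM on a log axis, with points for the 3 libraries of each group and bars for their mean. Krt5 lies at 6827 CPM on average in vehicle, 402 CPM at 6 h and 489 CPM at 12 h, while Hbegf goes from 233 to 1886 and then 1094 CPM.

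By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7776 of 10128 genes (76.8%) changed at 6 h, 3831 of them higher and 3945 lower. Among these, 1861 higher and 2130 lower genes changed at least 2-fold, and the median absolute log2 fold change of the called genes was 1.02. In 97.5% of the called genes the 3 libraries of one group all lay beyond the 3 of the other, as did 79.0% of all tested genes, where chance gives 10%. The largest rises were those of Slc6a14, an amino acid transporter, from 1.31 to 527 CPM (418-fold), Plet1, a surface protein of epithelial progenitors, with 2 reads in vehicle (ratio 444, 95% counting interval 122 to 3673), Cep295nl (127-fold), Rsad2, an antiviral enzyme (116-fold), Gpr153, an orphan receptor (97.6-fold), and Atp13a4, a P-type ATPase (94.8-fold). Among the largest falls were genes of proliferating cells. Pbk, a mitotic kinase, had no read at 6 h and was at least 358-fold lower, and Ns5atp9, a PCNA-binding protein, was at least 306-fold lower. Clspn, a replication checkpoint adaptor, kept 1 read (ratio 1022, interval 183 to 40410), as did the kinetochore gene Cenpt (860, interval 154 to 33990). The nuclease Exo1 kept 2 reads (465, interval 128 to 3841). Several of these values moved by more than 1.5 times without 1 library: Slc6a14 was 671-fold higher without vehicle replicate 3, Rsad2 209-fold without vehicle replicate 1 and Gpr153 63.6-fold or 194-fold without vehicle replicate 1 or 2. Plet1 had a ratio of 286 without vehicle replicate 1, and without PMA 6 h replicate 3 Pbk was at least 221-fold and Ns5atp9 at least 189-fold lower. Without the library that holds their reads at 6 h, Clspn was at least 238-fold (PMA 6 h replicate 2), Cenpt at least 195-fold (replicate 1) and Exo1 at least 217-fold lower (replicate 2), and without replicate 3 their ratios were 633, 532 and 287. All directions are relative to TMM scaling: with upper-quartile scaling the median gene shifted by -0.26 and without normalization by -0.54, which gave 2277 higher and 5855 lower genes and turned the direction of 261 calls. Changes smaller than these shifts, such as that of Icam1, depend on the scaling, and the medians of the lists called at 6 h kept their sign under every scaling tried.

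Lists of signalling genes were called higher at 6 h. Of the 20 immediate early and AP-1 genes, 19 rose, 0 fell (1 with upper-quartile scaling or without normalization) and Srf did not pass (-0.06). Their median log2 fold change was 2.36 (camera adjusted p = 6.4e-07; adjusted p = 0.237 with an estimated correlation). Atf3 stood at 6.12, Egr3 at 5.95 (7.06 without vehicle replicate 2), Fosb at 4.65 and Zfp36 at 3.89. Of 12 ERK feedback genes, 8 rose, 0 fell (2 with upper-quartile scaling, 3 without normalization) and 4 did not pass (median 1.99, adjusted p = 0.00224; adjusted p = 0.191 with an estimated correlation). Spry2 (4.66) and the MAP kinase phosphatases Dusp5 (4.41) and Dusp1 (3.99) led the list. Of 18 NF-kB and inflammatory genes, 15 rose and 2 fell (median 1.74, adjusted p = 0.00241; adjusted p = 0.597 with an estimated correlation). Cxcl2 (3.07), Nfkbiz (2.80) and Birc3 (2.78) were among those that rose, while the chemokine genes Ccl2 (-3.54) and Cxcl10 (-1.79; -1.20 without vehicle replicate 3) fell. Of 18 TGF-beta and BMP genes, 16 rose and 2 fell (median 1.30, with Bmp4 at its bound too; adjusted p = 0.00259; adjusted p = 0.237 with an estimated correlation). Smad7 (5.30) and Bambi (3.18), which inhibit the pathway, rose beside the ligands Inhba (4.17; 5.32 without vehicle replicate 1) and Bmp2 (3.67), and the receptor gene Tgfbr2 (-1.76) and Bmp7 (-0.64) fell. Bmp4 had no read in vehicle and was at least 6.24-fold higher, a call lost without PMA 6 h replicate 1 (fitted log2 fold change 3.31, at least 1.41-fold). The bound was 10.1-fold without PMA 6 h replicate 3 and 4.02-fold or 4.01-fold without vehicle replicate 1 or 2.

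Epithelial and tissue remodelling genes also moved. Of 14 mesenchymal transition and junction genes, 11 rose and 1 fell (median 1.97, adjusted p = 0.0011; adjusted p = 0.191 with an estimated correlation). Among those that rose were Cldn7 (5.04; 5.72 without vehicle replicate 3), Cldn4 (4.65) and Ocln (3.32) of tight junctions, while Snai2 (-3.56), a repressor of epithelial genes, fell. The transition factor Zeb1 (1.27) rose, and Snai1 (1.58) and Twist1 (0.61; 1.25 without vehicle replicate 1) did not pass. Of 18 matrix protease and plasminogen genes, 13 rose and 2 fell (median 1.53, adjusted p = 0.00482; adjusted p = 0.556 with an estimated correlation). The protease Mmp9 (5.81) and the urokinase receptor Plaur (4.61) rose, as did the protease inhibitors Serpinb2 (3.31) and Timp1 (3.28), and the matrix genes Tnc (-1.79) and Fn1 (-0.66) fell. Of 14 wound-activated and squamous genes, 10 rose and 3 fell (median 1.59, adjusted p = 0.0412; adjusted p = 0.596 with an estimated correlation). Cnfn (6.04) and Ivl (3.82) of the cornified envelope rose with S100a9 (5.27) and S100a8 (4.69), whereas Krt13 (-2.52) fell. Sprr3 (-1.16) was lower as well, a call lost without vehicle replicate 3 (-0.44) or any 1 of the 6 h libraries (-1.25 to -1.09). Krt4 (-0.89) was lower too, a call lost without any 1 vehicle library, PMA 6 h replicate 1 or PMA 12 h replicate 1 or 3 (-0.95 to -0.54).

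Lists of cell cycle, growth arrest and cholesterol genes were also called at 6 h. Of 22 DNA replication and S phase genes, 21 fell and 1 rose (median -3.16, adjusted p = 3.5e-06; adjusted p = 0.556 with an estimated correlation). Cdc45 stood at -6.03, Rrm2 at -5.99 and Tyms at -4.39. Gins2 (0.52) rose, a call lost with upper-quartile scaling and without normalization. Of 21 G2 and mitosis genes, 20 fell (15 by limma-voom) and 1 rose (median -4.31, adjusted p = 1.9e-04; adjusted p = 0.607 with an estimated correlation). Top2a stood at -7.84 (-7.20 without vehicle replicate 3), Cenpf at -6.77 (-5.88 without vehicle replicate 3, -7.63 without PMA 6 h replicate 3) and Ccna2 at -5.96. The exception was Cdc20, an activator of the anaphase-promoting complex, at 3.48 (4.15 without vehicle replicate 3). Its neighbour on the chromosome, Elovl1, went from 199 to 204 CPM in the vehicle libraries to 1917 to 2034 CPM. The vehicle libraries were unlike each other in these genes, among others: the mean log2 level of the G2 and mitosis list was 4.25, 5.31 and 6.23 in them against 1.73 to 1.80 at 6 h, and that of the S phase list was 5.44, 5.94 and 6.17 against 2.94 to 3.05. Without vehicle replicate 3 the median of the G2 and mitosis list relative to all genes went from -4.28 to -3.54. Of 14 CDK inhibitor and growth arrest genes, 10 rose and 2 fell (median 0.94, adjusted p = 0.0243; adjusted p = 0.597 with an estimated correlation). Gadd45b (5.18), Btg1 (4.37) and the CDK inhibitors Cdkn1c (3.08) and Cdkn2b (2.50) rose, while Gadd45a (-1.49) and Cdkn2a (-0.45) fell. Of 18 cholesterol synthesis genes, 13 fell and 3 rose (15 and 1 without normalization; median -0.76, adjusted p = 0.0136; adjusted p = 0.633 with an estimated correlation). The reductase Dhcr7 (-2.71) fell, and Insig1 (1.56), an inhibitor of the pathway, was among those that rose.

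Other lists did not pass as sets at 6 h although single members moved. Of 12 basal cell identity genes, 8 fell and 2 rose (0 rose with upper-quartile scaling or without normalization; median -0.51, adjusted p = 0.0646), with Krt15 at -1.59. Of 15 Wnt pathway genes, 11 fell and 3 rose (median -1.02, with Lgr5 at its bound too; adjusted p = 0.0738). The ligands Wnt3a (-5.25; -5.90 without PMA 6 h replicate 3) and Wnt10a (-2.28) fell, and the stem cell receptor Lgr5, without a read in vehicle, was at least 17.3-fold higher (11.1-fold without vehicle replicate 1 or 2). Its level stayed low, at 0.44 to 1.31 CPM in the 6 h libraries. The hemidesmosome and basement membrane list had 4 of 11 genes higher and 5 lower (2 and 6 with upper-quartile scaling, 1 and 8 without normalization; median -0.13, adjusted p = 0.698), with Col17a1 at -1.73 and Lamb3 at 1.49. Among 13 p63-activated genes, 4 rose and 7 fell (median -0.64, adjusted p = 0.565), and Tfap2c (2.97) was among those that rose. The EGF family had 4 of 9 genes higher and 4 lower (adjusted p = 0.769), its median at -0.06 while its mean of 0.29 and the test pointed up, with the receptor Erbb3 at 4.21 and the ligand Nrg1 at -3.53. Among 12 PKC and PKD genes 7 rose and 3 fell (5 fell with upper-quartile scaling or without normalization; median 0.84, adjusted p = 0.271), with the PKC substrate Marcks (2.40) among those that rose. In the Notch pathway 6 of 11 genes rose and 5 fell (median 0.48, adjusted p = 0.810), Mfng at 3.79 (4.90 without vehicle replicate 1) and Lfng at -3.13. Of 10 YAP and TEAD targets 5 rose and 4 fell (median 0.38, adjusted p = 0.611), Cyr61 at 1.76. The chromatin modifiers had 5 of 12 genes higher and 4 lower (3 and 7 without normalization; median 0.17, adjusted p = 0.640), with the maintenance methyltransferase Dnmt1 at -3.03 and the demethylase Kdm6b at 2.69. Interferon response genes split into 6 higher and 6 lower of 17 (4 and 9 with upper-quartile scaling, 4 and 12 without normalization; median -0.18 and test down, mean 0.35, adjusted p = 0.958), Rsad2 at 6.85 (7.71 without vehicle replicate 1) and Ifit2 at -3.41 (-2.82 without vehicle replicate 3). In the NRF2 and oxidative stress list 6 of 14 rose and 5 fell (median 0.29, adjusted p = 0.582), with Hmox1 at 2.34. In the unfolded protein and heat shock list 10 of 17 rose and 5 fell (median 0.74, adjusted p = 0.179), Hspb1 at 2.80. Reads of the near-identical Hspa1a (3.46) and Hspa1b (2.76) cannot be parted with certainty. Of 18 glycolysis and hypoxia genes 10 rose and 5 fell (7 and 9 without normalization; median 0.40, adjusted p = 0.220), with Vegfa at 2.36. Apart from the lists of other cell types, leaving out 1 library moved the smaller counts of 3 lists by more than 1.5 times. Without PMA 6 h replicate 2, 1 basal gene rose, and without vehicle replicate 3 or PMA 6 h replicate 1, 1 squamous gene fell. Without vehicle replicate 2 or 3 or PMA 6 h replicate 2 or 3, 3 unfolded protein and heat shock genes fell. At 6 h the counts adjusted over the list alone equalled those over all genes for every list. Without normalization the medians of the chromatin, YAP and TEAD, Notch, NRF2, glycolysis, sustentacular, immune and respiratory lists turned negative, and with upper-quartile scaling those of the chromatin and respiratory lists did.

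Markers of other cell types were mostly near the floor. In the neuronal list 13 of the 17 genes present in the files stayed under 1 CPM in every group, as did 7 of 14 sustentacular and gland genes, 9 of 12 respiratory and microvillar genes, 10 of 13 fibroblast and pericyte genes, 8 of 11 immune genes and 11 of 12 endothelial and glial genes. Of 4 tested neuronal genes 2 fell at 6 h and 0 rose (median -0.11 and test down, mean 0.04, adjusted p = 0.810), with Adcy3 at 192, 108 and 184 CPM in vehicle, 6 h and 12 h; the other, Tubb3 (-0.82), lost its call without vehicle replicate 2 (-0.75) or PMA 6 h replicate 1 (-0.71), and 1 gene rose without PMA 6 h replicate 3. Of 7 sustentacular and gland genes 4 rose and 3 fell (median 0.52, adjusted p = 0.507). Its most abundant member Krt8, a keratin of simple epithelia, stood at 1304, 1871 and 2150 CPM, and Krt18 (2.50) and Sox9 (2.01) rose with Cd24 (2.81), while the water channel Aqp3 (-2.57) fell. Of 3 respiratory and microvillar genes 1 fell (Trpm5 at -1.34; median 0.02, mean -0.42 and test down, adjusted p = 0.810). Of 3 fibroblast and pericyte genes 1 fell, or 2 without PMA 6 h replicate 3 or with upper-quartile scaling and 3 without normalization (median -1.04, adjusted p = 0.334), Col5a1 going from 20.9 to 0.535 CPM. Of 4 immune genes Cd68 (1.83) rose and Cd14 (-2.40) fell (median 0.27 and test up, mean -0.01, adjusted p = 0.917). The 1 measured endothelial and glial gene, the VEGF receptor Kdr, had no read in vehicle and 0.632 CPM at 6 h (at least 13.9-fold higher, or 8.97-fold or 8.95-fold without vehicle replicate 1 or 2; its fitted value of 6.43 becomes 3.80 at that bound).

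**Figure D2:**
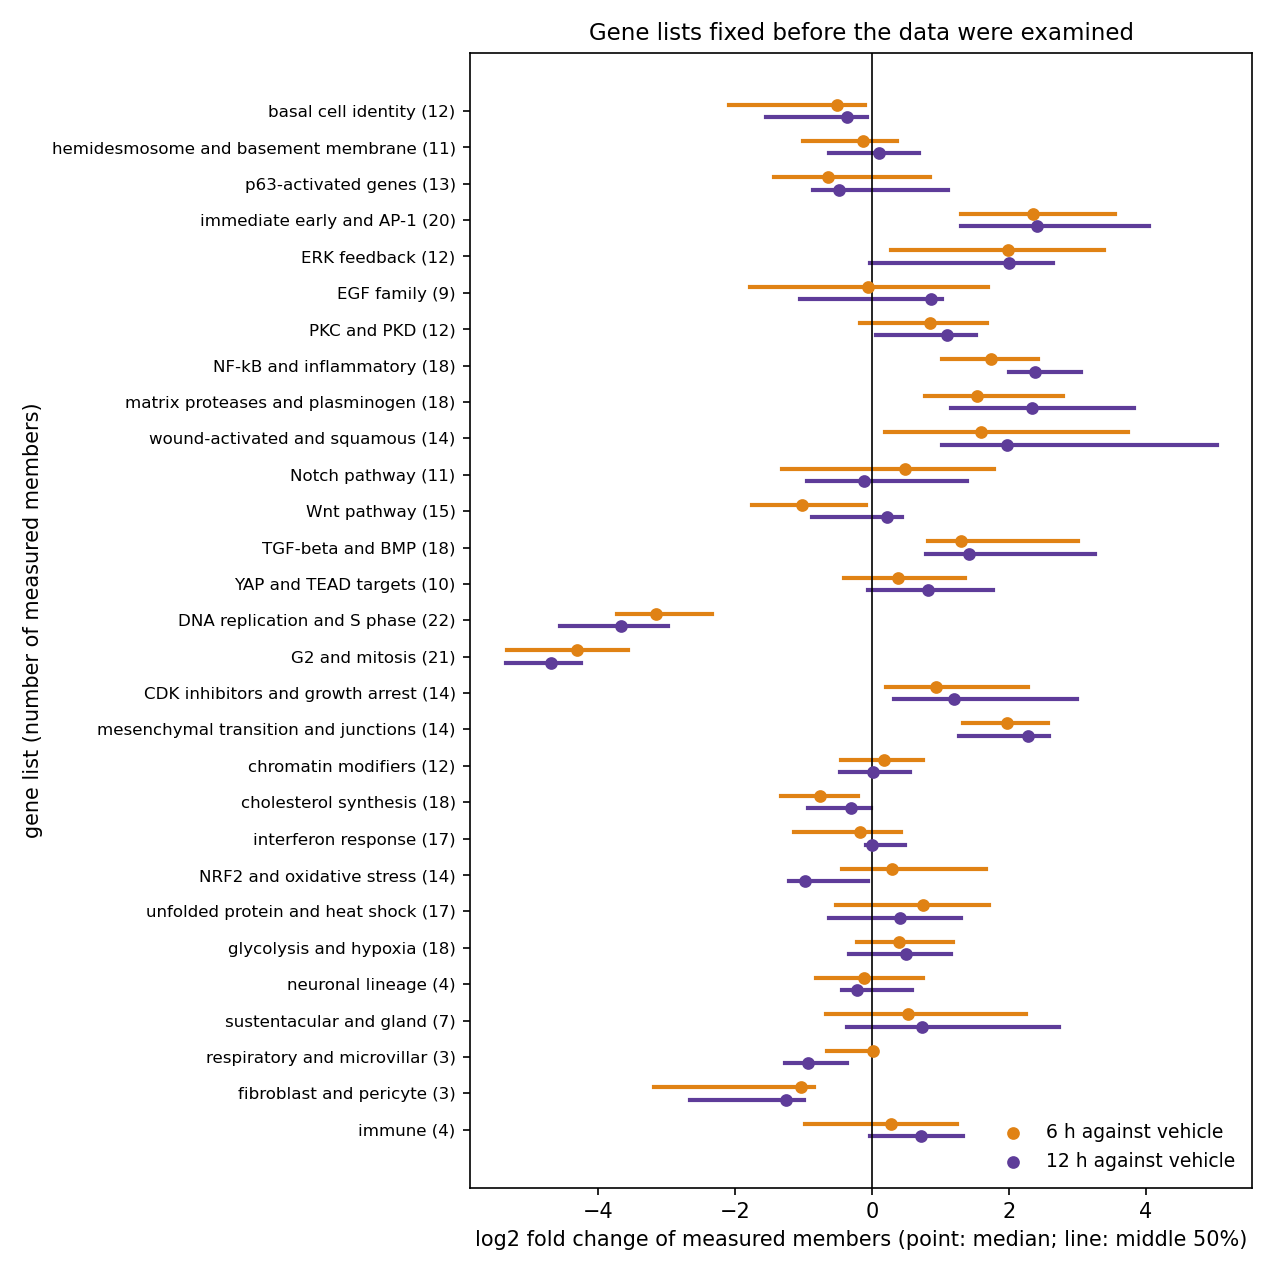
Median log2 fold change of the measured members of each gene list, with lines for the middle of the distribution, at 6 h and 12 h of PMA against vehicle. The G2 and mitosis list lies at -4.31 and -4.70 and the immediate early and AP-1 list at 2.36 and 2.41.

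The second comparison asks how the cells stood after 12 h of PMA. Basal keratins were still far below vehicle: Krt5 stood at 489 ± 92.2 CPM (-3.80 ± 0.15, adjusted p = 2.2e-10) and Krt14 at 1014 ± 105 CPM (-2.39 ± 0.10, adjusted p = 4.9e-13). Tp63 was at 90.7 ± 4.72 CPM (-1.27 ± 0.09, adjusted p = 8.0e-10). Icam1 rose to 359 ± 40.5 CPM (1.33 ± 0.10, adjusted p = 1.2e-09), Hbegf stood at 1094 ± 10.7 CPM (2.23 ± 0.07, adjusted p = 2.8e-14) and Myc at 475 ± 13.0 CPM (1.40 ± 0.07, adjusted p = 8.3e-12). Fosl1 at 278 ± 5.67 CPM (0.25 ± 0.08, adjusted p = 0.0122) lost its call without vehicle replicate 1 (0.18) or 2 (0.22) and its sign with upper-quartile scaling (-0.02) or without normalization (-0.33). Sox2 at 1.46 ± 0.218 CPM (-0.99 ± 0.39, adjusted p = 0.0281) lost its call without vehicle replicate 2 (-0.87) or 3 (-0.9958) or PMA 12 h replicate 2 (-1.02) or 3 (-0.88).

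At 12 h 7682 genes (75.8%) changed, 3818 higher and 3864 lower, of which 1820 and 2065 changed at least 2-fold. The groups did not overlap in 97.6% of the called genes and 78.7% of all genes, where chance gives 10%. Slc6a14 (633-fold), Gpr153 (271-fold), Cnfn (257-fold), the tetraspanin-like Tm4sf1 (214-fold) and Rsad2 (169-fold) rose most, together with Plet1 (ratio 245, interval 67.2 to 2030). The kinetochore gene Cenpf was at least 372-fold lower and the mitotic kinesin gene Kif2c at least 200-fold lower, with no read at 12 h. Exo1 kept 1 read (ratio 819, interval 147 to 32390), Pbk 2 (473, interval 131 to 3910) and Clspn 3 (300.5, interval 103 to 1459), and the kinesin gene Kif15 was 209-fold lower (393-fold without PMA 12 h replicate 2). Without vehicle replicate 3, Slc6a14 was 1018-fold and Tm4sf1 422-fold higher, and Cenpf at least 212-fold lower. Rsad2 was 306-fold higher without vehicle replicate 1, Gpr153 177-fold or 541-fold without vehicle replicate 1 or 2, and Plet1 had a ratio of 158 without vehicle replicate 1. Without PMA 12 h replicate 1 or 2 the bounds fell to 235-fold and 244-fold for Cenpf and 126-fold and 131-fold for Kif2c. Without PMA 12 h replicate 1 the ratios were 518 for Exo1, 299 for Pbk and 570.2 for Clspn, and without replicate 2, which holds their reads, Exo1 was at least 179-fold and Pbk at least 207-fold lower. Upper-quartile scaling shifted the median gene by -0.27 and no normalization by -0.58, with 2120 genes higher, 6021 lower and 368 calls turned.

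Of the 11 lists called at 6 h, 10 were called again at 12 h. Of 20 immediate early and AP-1 genes 19 rose, 0 fell (2 without normalization) and Fosl2 (0.34) did not pass (median 2.41, adjusted p = 6.4e-07; adjusted p = 0.237 with an estimated correlation). Atf3 stood at 5.66, Egr3 at 5.14 (6.25 without vehicle replicate 2) and Egr2 at 5.05 (4.44 or 5.67 without vehicle replicate 2 or 3). ERK feedback genes had 8 of 12 higher and 2 lower (7 and 4 without normalization; median 2.01, adjusted p = 0.0151; adjusted p = 0.237 with an estimated correlation). Spry2 stood at 3.54 and Dusp5 at 3.34, while Spred2 (-0.81) and the ERK target Etv4 (-0.45) fell. Among 18 NF-kB and inflammatory genes 16 rose and 1 fell (median 2.39, adjusted p = 1.9e-04; adjusted p = 0.556 with an estimated correlation). The chemokine Ccl20 stood at 5.72 and the cytokine Csf2 at 4.08, and Cxcl10 (-2.88; -2.30 without vehicle replicate 3) was lower. TGF-beta and BMP genes had 15 of 18 higher and 3 lower (median 1.41, also with Bmp4 at its bound of at least 13.6-fold, or 8.77-fold or 8.75-fold without vehicle replicate 1 or 2; adjusted p = 0.00535; adjusted p = 0.237 with an estimated correlation). Inhba stood at 6.02 (7.17 without vehicle replicate 1) and Bmp2 at 5.90, while Bmp7 (-0.86), Tgfbr2 (-0.70) and Id2 (-0.57) fell. Id2 lost its call without vehicle replicate 1 or 3 or PMA 12 h replicate 2 or 3 (-0.57 to -0.49). Matrix protease and plasminogen genes had 14 of 18 higher and 3 lower (median 2.34, adjusted p = 0.00659; adjusted p = 0.568 with an estimated correlation). The metalloproteases stood high, Mmp9 at 6.81, Mmp10 at 5.10 (5.87 without vehicle replicate 3) and Mmp12 at 4.36, and Tnc (-2.21) and Fn1 (-1.16) were among those that fell. In the wound-activated and squamous list 11 of 14 rose and 3 fell (median 1.96, adjusted p = 0.0187; adjusted p = 0.556 with an estimated correlation). Cnfn stood at 8.01, S100a8 at 6.55, S100a9 at 6.54 and Ivl at 5.06, whereas the keratins Krt13 (-2.78), Krt4 (-2.17) and Krt17 (-0.56) fell. All 14 mesenchymal transition and junction genes passed, 13 higher and 1 lower (median 2.28, adjusted p = 5.2e-04; adjusted p = 0.191 with an estimated correlation). Cldn4 stood at 4.55 and Cldn7 at 4.23 (4.91 without vehicle replicate 3), the transition factors Snai1 (2.64) and Zeb1 (2.61) rose as well, and Snai2 (-1.39) fell.

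Both cell cycle lists were called lower again at 12 h. All but Gins2 (-0.02) of 22 S phase genes fell and 0 rose (median -3.67, adjusted p = 3.8e-07; adjusted p = 0.525 with an estimated correlation). Cdc45 stood at -5.77 and the helicase subunits Mcm3 at -5.11 and Mcm6 at -5.08. Of 21 G2 and mitosis genes 20 fell (12 by limma-voom) and Cdc20 (3.40; 4.07 without vehicle replicate 3) rose (median -4.70, with Cenpf at its bound too; adjusted p = 7.1e-05; adjusted p = 0.597 with an estimated correlation). Top2a stood at -7.46 (-6.82 without vehicle replicate 3) and Mki67 at -6.07. The vehicle spread given above applies here too, against mean log2 levels of 1.47 to 1.61 (G2 and mitosis) and 2.41 to 2.66 (S phase) at 12 h, and without vehicle replicate 3 the G2 and mitosis median relative to all genes went from -4.68 to -3.98. CDK inhibitor and growth arrest genes had 10 of 14 higher and 1 lower (2 lower with upper-quartile scaling, 4 without normalization; median 1.19, adjusted p = 0.0062; adjusted p = 0.587 with an estimated correlation). Gadd45b stood at 6.44, Btg1 at 3.50 and Cdkn1c at 3.31, and Gadd45a (-0.80) was lower.

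The cholesterol synthesis list no longer passed at 12 h, with 3 of 18 genes higher and 10 lower (2 and 16 without normalization; median -0.31, adjusted p = 0.142). Basal cell identity genes had 2 of 12 higher and 6 lower (1 and 9 without normalization; median -0.37, adjusted p = 0.190), with Krt15 at -2.96, and NRF2 and oxidative stress genes 3 of 14 higher and 10 lower (median -0.99, adjusted p = 0.239), with the glutathione reductase gene Gsr at -2.15. YAP and TEAD targets had 5 of 10 higher and 1 lower (4 lower with upper-quartile scaling, 5 without normalization; median 0.82, adjusted p = 0.0921), Cyr61 at 4.77 and Ctgf at 3.26. The 15 Wnt pathway genes split into 6 higher and 6 lower (3 and 6 with upper-quartile scaling, 3 and 8 without normalization; median 0.21 and mean 0.25 but test down, adjusted p = 0.881), with Lgr5 at 0.87 to 1.60 CPM and at least 27.2-fold higher (17.5-fold without vehicle replicate 1 or 2). In the p63-activated list 6 of 13 rose and 6 fell (median -0.48 and mean -0.18 but test up, adjusted p = 0.985). Notch pathway genes had 3 of 11 higher and 4 lower (7 lower with upper-quartile scaling or without normalization; median -0.12 and test down, mean 0.12, adjusted p = 0.899), and chromatin modifiers 5 of 12 higher and 5 lower (3 and 6 with upper-quartile scaling, 3 and 7 without normalization; median 0.01 and test up, mean -0.03, adjusted p = 0.919). The remaining counts at 12 h were 4 higher and 4 lower of 11 hemidesmosome genes (adjusted p = 0.794), 6 and 3 of 9 EGF family genes (adjusted p = 0.334), 7 and 2 of 12 PKC and PKD genes (adjusted p = 0.110), 5 and 3 of 17 interferon response genes (adjusted p = 0.484), 9 and 4 of 17 unfolded protein and heat shock genes (adjusted p = 0.364) and 10 and 5 of 18 glycolysis and hypoxia genes (adjusted p = 0.364). Among the other cell types, Kdr reached 2.50 CPM (at least 52.8-fold higher, or 34.0-fold without vehicle replicate 1 or 2; fitted value 8.38, 5.72 at the bound), and the neuronal list, whose median of -0.22 and test pointed down against a mean of 0.37, had 1 of 4 genes higher. Sustentacular and gland genes had 4 of 7 higher and 2 lower, respiratory and microvillar genes 2 of 3 lower (1 adjusted over the list alone), fibroblast and pericyte genes 2 of 3 lower and immune genes 1 higher and 1 lower of 4, with adjusted p from 0.313 to 0.954 for these 5 lists. The respiratory gene Trpm5 (-0.93) lost its call without any 1 of vehicle replicates 2 and 3, PMA 6 h replicate 2 and PMA 12 h replicates 2 and 3 (-1.06 to -0.63), and the fibroblast gene Col1a1 (-1.26) without vehicle replicate 1 (-1.002) or PMA 12 h replicate 1 (-1.13) or 2 (-0.89), and stood at -1.92 without PMA 12 h replicate 3. Leaving out 1 library also moved the number of lower genes to 1 for PKC and PKD (without vehicle replicate 1 or PMA 12 h replicate 1), 2 for CDK inhibitors (without vehicle replicate 1 or PMA 6 h replicate 1), 7 for the unfolded protein list (without vehicle replicate 1) and 1 for the neuronal list (without PMA 12 h replicate 2). Without normalization the counts were 2 higher and 6 lower for the hemidesmosome list, 6 and 5 for PKC and PKD, 3 and 7 for interferon response, 6 and 7 for unfolded protein and heat shock, 6 and 8 for glycolysis and hypoxia and 1 and 3 for neuronal genes (1 and 2 with upper-quartile scaling). Elsewhere at 12 h the counts adjusted over the list alone were those over all genes. The medians of the hemidesmosome, Wnt, chromatin and interferon lists turned negative with upper-quartile scaling, and without normalization those of the glycolysis and unfolded protein lists did as well.

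The third comparison asks directly what differed between 12 h and 6 h of PMA. Tp63 rose by 0.92 ± 0.09 (adjusted p = 4.1e-07), Krt14 by 0.38 ± 0.09 (adjusted p = 0.00256) and Icam1 by 1.03 ± 0.10 (adjusted p = 1.9e-07), while Krt5 (0.28 ± 0.14, adjusted p = 0.108) and Sox2 (1.07 ± 0.46, adjusted p = 0.0629) did not pass. Hbegf fell by 0.79 on the log2 scale (SE 0.07, adjusted p = 1.1e-07) and Fosl1 fell by 1.06 (SE 0.08, adjusted p = 2.9e-08), whereas Myc rose by 0.61 ± 0.07 (adjusted p = 1.6e-06). The largest rises from 6 h to 12 h were the following. Cxcl12, a chemokine, went from 0.502 to 20.9 CPM (39.3-fold, 63.9-fold without PMA 6 h replicate 3, vehicle 0.922 CPM). Csf1, a growth factor of macrophages, went from 0.709 to 9.01 CPM (13.3-fold, 27.9-fold without PMA 6 h replicate 2, vehicle 8.53), the matrix glycoprotein gene Thbs1 from 3.36 to 39.9 CPM (12.0-fold, vehicle 51.1), the galectin gene Lgals9 from 0.820 to 9.09 CPM (11-fold, vehicle 10.4), Wnt3a from 0.378 to 4.10 CPM (10.3-fold, 16.1-fold without PMA 6 h replicate 3, vehicle 15.2) and the endosomal gene Plekhf1 from 0.618 to 6.13 CPM (9.79-fold, vehicle 11.7).

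Genes that were lower at 12 h than at 6 h included transient responders. Thbd, the thrombin receptor thrombomodulin, went from 139 to 12.1 CPM (11.5-fold lower, vehicle 22.4), the small heat shock protein gene Hspb1 from 851 to 119 CPM (7.17-fold, vehicle 122) and the pseudokinase gene Trib1 from 249 to 37.3 CPM (6.69-fold, vehicle 4.85). The ligand gene Epgn (5.33-fold) and the cytokinesis kinase gene Cit (5.31-fold), already below vehicle at 6 h, fell further, as did the mitotic helicase gene Ercc6l (5.84-fold, adjusted p = 0.0222). The Ercc6l call was lost without any 1 of PMA 6 h replicates 1 and 3 and PMA 12 h replicates 1, 2 and 3 (log2 fold changes from -2.82 to -2.18). In all, 5175 genes (51.1%) differed, 2561 higher and 2614 lower at 12 h, of which 616 and 551 differed at least 2-fold, with a median absolute log2 fold change of 0.63. The groups did not overlap in 96.1% of the called genes and 58.0% of all genes, where chance gives 10%, and the largest shift of the median gene under another scaling was -0.04.

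Between 6 h and 12 h 7 lists passed. All 9 of the Wnt pathway genes that changed, of 15, rose (median 0.63, adjusted p = 0.0016; adjusted p = 0.191 with an estimated correlation). Wnt3a stood at 3.36 (4.01 without PMA 6 h replicate 3), the Wnt inhibitor Rnf43 at 2.43, Wnt7a at 1.94 and Wnt4 at 0.98. YAP and TEAD targets had 7 of 10 higher and 1 lower (8 and 1 adjusted over the list alone; median 0.58, adjusted p = 0.00589; adjusted p = 0.568 with an estimated correlation). The matricellular genes Cyr61 and Ctgf stood at 3.01 and 2.23, and the kinase gene Nuak2 (-0.57) was lower. Hemidesmosome and basement membrane genes had 8 of 11 higher and 1 lower (median 0.65, adjusted p = 0.0208; adjusted p = 0.597 with an estimated correlation). The laminin chain gene Lamb3 (1.07) rose, and the anchoring fibril gene Col7a1 (-0.58) was lower, a call lost without PMA 6 h replicate 2 or PMA 12 h replicate 1 or 2. Cholesterol synthesis genes had 12 of 18 higher and 1 lower (median 0.42, adjusted p = 0.00638; adjusted p = 0.597 with an estimated correlation). Dhcr7 (0.95) and the inhibitor Insig1 (1.12) were among those that rose. In the NRF2 and oxidative stress list 10 of 14 fell and 0 rose (11 adjusted over the list alone; median -0.79, adjusted p = 2.7e-04; adjusted p = 0.197 with an estimated correlation). The list was led by Srxn1 (-2.28), the cystine transporter Slc7a11 (-1.98) and the glutathione enzyme Gclc (-1.61). ERK feedback genes had 9 of 12 lower and 1 higher (median -0.64, adjusted p = 0.0033; adjusted p = 0.191 with an estimated correlation). Dusp6 stood at -1.36, Dusp1 at -1.12 and Spry2 at -1.11, and Spry1 (2.10) was higher. S phase genes had 10 of 22 lower and 1 higher (11 and 1 adjusted over the list alone, 6 and 0 by limma-voom, 11 and 2 by DESeq2, 13 and 2 by limma-trend; median -0.63, adjusted p = 0.0243; adjusted p = 0.715 with an estimated correlation). Mcm7 stood at -1.80 and Pcna at -1.48, and Cdc6 (0.62) was higher. This last list no longer passed as a set without PMA 12 h replicate 3, where 6 genes fell and 2 rose, and 14 and 12 genes fell without vehicle replicates 1 and 3.

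Of 21 G2 and mitosis genes only the kinase gene Aurka (-2.05) changed between the times (median -0.41, also with Cenpf at its bound; adjusted p = 0.534). Without vehicle replicate 1, 4 of them fell and 2 rose, and without vehicle replicate 3, 3 fell and 2 rose, while DESeq2 and limma-trend gave 2 lower and 1 higher and limma-voom 0. With only the 6 PMA libraries fitted 4 fell and 2 rose. The 20 immediate early and AP-1 genes split into 9 higher and 7 lower (8 lower adjusted over the list alone; median -0.16, adjusted p = 0.985), Fosb at -1.97 and Egr2 at 1.54. Of 18 NF-kB and inflammatory genes 10 rose and 1 fell (2 fell adjusted over the list alone or under any other scaling; median 0.37, adjusted p = 0.0896), with Ccl20 at 5.98 (8.23 or 5.32 without PMA 6 h replicate 2 or 3) and Ccl2 at 3.78 (2.96 without PMA 12 h replicate 2). In the wound-activated and squamous list 8 of 14 rose and 2 fell (3 fell adjusted over the list alone; median 1.25, adjusted p = 0.113), with Sprr3 at 2.66, Sbsn at 2.10 and Cnfn at 1.97. Matrix protease and plasminogen genes had 8 of 18 higher and 4 lower (9 and 4 adjusted over the list alone; adjusted p = 0.651), Mmp1 at 2.29 (2.92 without PMA 6 h replicate 2) and Mmp10 at 2.26. Median, mean and test did not share a sign in the following lists. They were TGF-beta and BMP (5 higher and 6 lower of 18, 6 and 8 adjusted over the list alone; median -0.03, mean 0.23, test up), Notch pathway (5 and 4 of 11, 6 and 4 adjusted over the list alone; median 0.18, mean -0.08, test up), mesenchymal transition and junctions (3 and 4 of 14, 4 and 4 adjusted over the list alone; median -0.07, mean 0.15, test down) and respiratory and microvillar (1 of 3 lower; median 0.14, mean -0.36, test down). Further such lists were the unfolded protein and heat shock list (5 and 6 of 17; median 0.07, mean -0.11, test down) and the glycolysis and hypoxia list (7 and 6 of 18; median 0.00, mean -0.22, test down). Basal cell identity genes had 6 of 12 higher and 3 lower (7 and 3 adjusted over the list alone), p63-activated genes 5 and 2 of 13 (6 and 2 adjusted over the list alone), chromatin modifiers 0 and 5 of 12, interferon response genes 5 and 2 of 17 and CDK inhibitor genes 6 and 2 of 14. Sustentacular and gland genes had 3 of 7 higher (2 adjusted over the list alone), immune genes 2 of 4, neuronal genes 2 higher and 1 lower of 4, and fibroblast and pericyte genes 1 of 3 higher; Kdr rose by 1.95 (adjusted p = 0.00418). None of the lists in this paragraph passed, and the counts of the EGF family (4 higher and 5 lower of 9) and of PKC and PKD (5 and 2 of 12, 3 and 2 without normalization) were not called as sets either. Smaller counts here also moved when 1 library was left out. Without PMA 6 h replicate 3, 5 protease genes rose, and without PMA 6 h replicate 2 or PMA 12 h replicate 2, 3 PKC and PKD genes rose. From 2 to 3 NF-kB genes fell without vehicle replicate 1 or 3, PMA 6 h replicate 3 or PMA 12 h replicate 2, and 1 squamous gene fell without PMA 6 h replicate 2 or any 1 PMA 12 h library. Among chromatin modifiers 1 rose without vehicle replicate 1 or 3 or PMA 6 h replicate 3. The neuronal genes Ncam1 (1.34; 0.96 to 1.58 without vehicle replicate 2 or any 1 PMA library) and Gnal (-1.22; -1.14 to -0.99 without PMA 6 h replicate 1 or PMA 12 h replicate 1 or 3) lost their calls, as did the immune gene Cd68 (0.31) without PMA 12 h replicate 1 (0.25), and Col5a1 without the libraries named with its class. Without PMA 12 h replicate 3, 1 fibroblast gene fell.

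**Figure D3:**
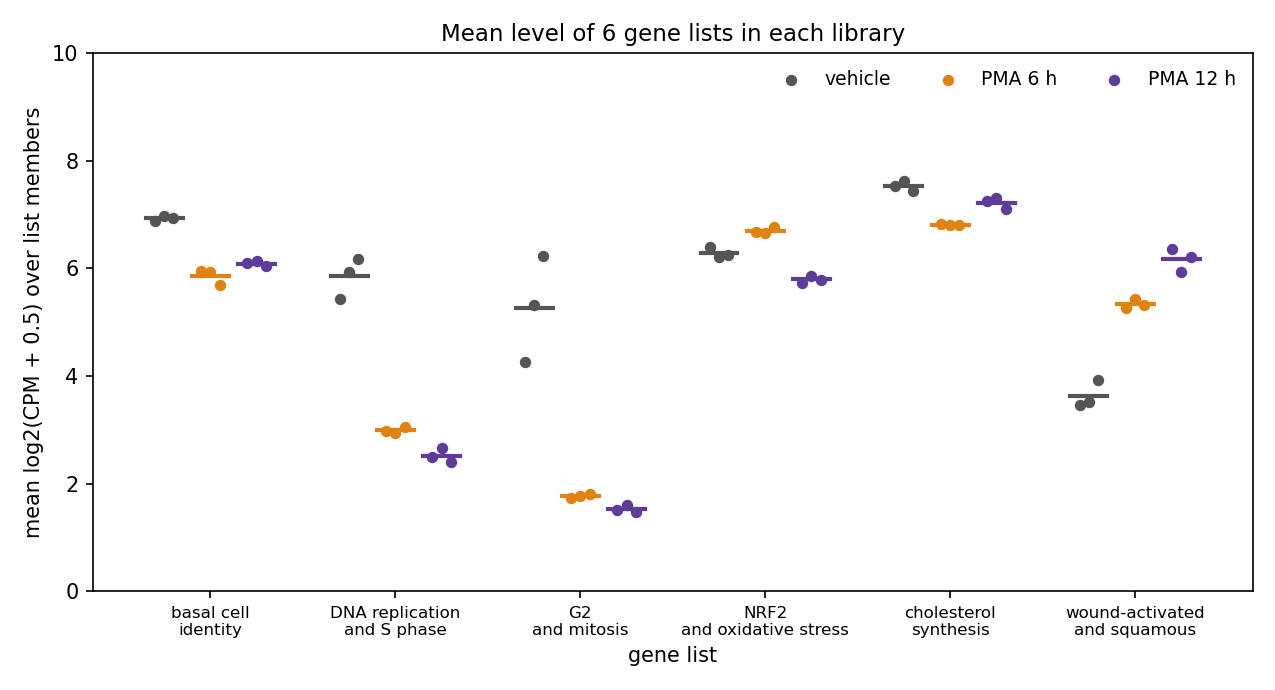
Mean log2(CPM + 0.5) over the measured members of 6 gene lists in each library, with points for the 3 libraries of each group. The G2 and mitosis list spans 4.25 to 6.23 in the vehicle libraries and lies at 1.47 to 1.80 in the 6 PMA libraries, while the wound-activated and squamous list lies at 3.46 to 3.93 in vehicle and 5.93 to 6.35 at 12 h.

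The 3 groups form a time course, and the calls of the 3 comparisons were combined into classes. A gene that rose at 6 h and then fell towards 12 h was called transient up, as were 1519 genes, among them Fbxo32, a muscle-type ubiquitin ligase subunit (1.26, 116 and 79.9 CPM in vehicle, 6 h and 12 h), the membrane-anchored semaphorin gene Sema7a (14.3, 1249 and 887 CPM), Atf3 (3.23, 226 and 164 CPM) and Plet1 (0.0320, 13.6 and 7.54 CPM). The transient classes, up and down, do not require a return to the vehicle level. Each gene named here for these classes was still called in its first direction at 12 h against vehicle. Progressive up held 749 genes that rose further, with Gpr153 (0.200, 20.1 and 56.1 CPM), Cnfn (0.716, 46.0 and 180 CPM), Slc6a14 (1.31, 527 and 797 CPM) and the neuropeptide gene Calcb (0.220, 12.3 and 19.1 CPM). Sustained up held 1421 genes, with Prdm1, a transcriptional repressor that acts in epidermal and lymphoid differentiation (11.1, 697 and 645 CPM), Rsad2, Atp13a4 and Cep295nl. Late up held 432 genes without a call at 6 h, with Cxcl12, Spry1 (2.11, 2.7 and 11.6 CPM), the chloride channel regulator gene Clca4l (7.29, 12.2 and 46.2 CPM) and the phosphatase gene Acpp (48.9, 56.2 and 230 CPM). Transient down held 1319 genes, with the matricellular gene Wisp1 (19.7, 0.378 and 2.03 CPM), Cdca7l (27.9, 0.464 and 1.19 CPM), Dctd (14.8, 0.357 and 1.11 CPM) and Col5a1 (20.9, 0.535 and 1.24 CPM). Progressive down held 608 genes, with the chromatin assembly gene Chaf1b (23.8, 1.01 and 0.391 CPM), the centromere gene Hjurp (29.4, 1.40 and 0.483 CPM), Ddias (32.1, 1.64 and 0.488 CPM) and Mcm3 (113, 5.93 and 3.22 CPM). Sustained down held 1824 genes, with Pbk, Ns5atp9, Clspn and Cenpt. Late down held 421 genes, with the glucuronosyltransferase gene Ugt1a6 (23.4, 18.8 and 4.09 CPM), the chemokine receptor gene Ackr3 (32.3, 27.7 and 7.99 CPM), Krt19 (11.8, 8.29 and 3.09 CPM) and Pir (13.2, 12.3 and 3.52 CPM). Together the 8 classes held 8293 genes, 777 had other combinations and 1058 had no call, while 20 simulations without any effect put 0.05 genes on average into the classes.

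Several of these class memberships were lost at the step from 6 h to 12 h when 1 library was left out. By edgeR's test on all libraries, the adjusted p of that step was 0.0285 for Slc6a14, 0.035 for Calcb, 0.0444 for Hjurp and 0.0236 for Ddias. These calls lay near the threshold and did not hang on 1 particular library. That step lost its call for Slc6a14 (log2 fold change 0.60) without any 1 of 7 libraries, namely vehicle replicate 2 and each of the 6 PMA libraries (0.55 to 0.64). It was lost for Calcb (0.63) without any 1 PMA library (0.49 to 0.72). The same held for Hjurp (-1.49; -1.82 to -1.23) and Ddias (-1.76; -2.07 to -1.36) without any 1 PMA library. Chaf1b (-1.35) lost it without PMA 6 h replicate 3 or PMA 12 h replicate 1 or 3 (-1.11 to -1.05), Mcm3 (-0.87) without PMA 6 h replicate 2 or 3 or PMA 12 h replicate 1 or 3 (-0.81 to -0.64), Cdca7l (1.46) without PMA 6 h replicate 2 or 3 or PMA 12 h replicate 1 or 2 (0.94 to 1.56), Dctd (1.68) without PMA 6 h replicate 3 or PMA 12 h replicate 1 or 3 (1.01 to 1.77), and Col5a1 (1.27) without PMA 6 h replicate 3 (0.80) or PMA 12 h replicate 1 (1.11). Chaf1b stood at -2.13 without PMA 12 h replicate 2 and Cdca7l at 2.05 without PMA 6 h replicate 1.

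The last comparisons ask how far the changes at 6 h and 12 h overlapped. Of the called genes, 6202 changed the same way at both times, 3073 up and 3129 down, where independent draws would give 1444 up and 1505 down. The split depends on the scaling, with 2333 up and 4020 down by upper-quartile scaling and 1630 up and 5125 down without normalization. A further 313 genes changed in opposite directions. The list members Id2 (0.73 at 6 h and -0.57 at 12 h), Sprr3 (-1.16 and 1.5; 2.21 at 12 h without vehicle replicate 3) and Cdkn2a (-0.45 and 0.90) were among the latter and are named after their values were seen. As given with their lists, the calls of Id2 at 12 h and of Sprr3 at 6 h were lost when some single libraries were left out. Both comparisons use the same 3 vehicle libraries, which cannot be split into 2 parts of 2 libraries. Part of the excess may come from the shared controls, and the excess by itself is not a shared effect. In the simulations without an effect the shared controls gave 0 genes called the same way, a correlation of the log2 fold changes across genes of 0.439 and a covariance of 0.0333, against an observed correlation of 0.875 and covariance of 2.14. Genes are not independent replicates, and it is the difference of the covariances that estimates the shared effect. Over the 3 groups as a whole 8843 genes differed by the same edgeR test.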

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

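The counts of other splits were planned, and the comparison of reads outside annotated exons was chosen after the result was seen. These results stand out because levels after 12 h in PMA differed from those after 6 h in a direct test, edgeR's for genes and camera's for lists, where time in culture is not separated from PMA. In all, 5175 genes differed between the times. Splitting the 6 PMA libraries otherwise, 3 against 3, called at most 0 genes by edgeR, but 10 splits are too few for a share under 0.05 (the real split is 1 of 10). Further, 313 genes were called in opposite directions at 6 h and 12 h against vehicle.

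Among the lists, the step from 6 h to 12 h had a median log2 fold change of 0.65 for hemidesmosome and basement membrane genes, 0.63 for Wnt pathway genes, 0.58 for YAP and TEAD targets and 0.42 for cholesterol synthesis genes. It was -0.64 for ERK feedback genes, -0.63 for DNA replication and S phase genes and -0.79 for NRF2 and oxidative stress genes. With an estimated correlation none of these 7 lists was called (adjusted p from 0.191 to 0.715). In the panel, Icam1 (1.03), Tp63 (0.92), Myc (0.61) and Krt14 (0.38) were higher at 12 h than at 6 h, and Hbegf (-0.79) and Fosl1 (-1.06) were lower. The receptor gene Thbd differed by -3.52, above vehicle at 6 h and below it at 12 h.

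Outside the data that the comparisons use, vehicle was exceeded in the share of uniquely mapped reads outside annotated exons. This share was 20.2% on average at 6 h (19.7% to 20.7%) and 20.8% at 12 h (19.9% to 21.3%), against 19.2% in vehicle (at most 19.6%). Each PMA library lay above the 3 vehicle libraries, which was noticed in the values and not tested.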

How the results depend on the processing

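All alternatives in this part were planned, and the check of the replicate numbers and the simulated recovery by level and depth were chosen after the result was seen. Apart from the fold change limit, no alternative moved the number of genes called at 6 h, at 12 h, between the times or over the 3 groups by more than 1.5 times. Across tools, filters, scalings and count columns, 7258 to 8132 genes were called at 6 h, 7119 to 8141 at 12 h, 4585 to 5253 between the times and 8301 to 9078 over the 3 groups. Of the 7776 calls at 6 h, DESeq2 shared 7619 with their direction and limma-voom 7715; at 12 h they shared 7545 and 7610 of 7682, and between the times 5037 and 4864 of 5175. DESeq2 gave no adjusted p to 1012, 1518 and 1771 genes in the 3 comparisons, which its own filter set aside.

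Leaving out 1 library at a time gave 7349 to 7865 genes at 6 h, 7259 to 7830 at 12 h, 4623 to 5275 between the times, 8511 to 8811 over the 3 groups, 5791 to 6195 changed the same way at both times and 27 to 29 list calls. The temporal classes held 7884 to 8176 genes: transient up 1366 to 1517, progressive up 637 to 747, sustained up 1336 to 1541, late up 378 to 475, transient down 1179 to 1310, progressive down 480 to 610, sustained down 1720 to 1998 and late down 362 to 452. The list call that was lost was that of S phase genes between the times without PMA 12 h replicate 3.

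A log2 fold change of at least 1 left 3991 genes at 6 h, 3885 at 12 h, 1167 between the times and 2830 changed the same way at both times, since fewer genes pass. The classes then held 3468 genes, with 202 transient up, 98 progressive up, 137 late up, 291 transient down, 83 progressive down and 178 late down, while both sustained classes stayed within 1.5 times.

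Scaling moved directions. Without normalization 6222 of the calls at 6 h and 5984 of those at 12 h kept their direction and 261 and 368 turned. Progressive up then held 369 genes, sustained up 733, late up 254, progressive down 1184 and sustained down 2837. The shift of the median gene by -0.54 at 6 h and -0.58 at 12 h, which this alternative leaves in, moves genes from the rising to the falling classes. That shift, larger than their change, also turned Icam1 at 6 h (-0.24), Acpp at 6 h (-0.33) and Fosl1 at 12 h (-0.33; -0.019 with upper-quartile scaling). Dctd between the times turned with the second strand column (-0.91), and the cause was not tested. With a correlation estimated from the data, camera called 0 list tests instead of 28 (11 at an unadjusted p under 0.05, and 76 by fry). With an estimated correlation camera also takes its degrees of freedom from the residuals, so both change at once, and which of them ended the calls was not tested.

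For the lists, the other 1588 values in the alternatives stayed on their side of the threshold, 30 changed sign without a call and 6 passed newly: basal identity (without normalization, and without PMA 6 h replicate 1), Wnt (no filter, and the first strand column) and unfolded protein and heat shock (without normalization) at 6 h, and NF-kB between the times (no filter). Counts of rising or falling list members that moved by more than 1.5 times under a scaling are given with the lists. Under another tool, filter, column or set of fitted libraries, the further counts that moved so far, apart from those given with the S phase and G2 and mitosis lists, were of at most 5 genes. Of the values of named genes 8148 were the same, 176 lost their call, 37 gained it, 3 changed sign without a call and the 5 above reversed.

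The values gave no sign that the replicate numbers pair the libraries: deviations from the group mean correlated at -0.115 to 0.0271 between same-numbered and -0.0724 to 0.0875 between differently numbered libraries of other groups. Whether same-numbered libraries shared an animal, culture or day cannot be told from these correlations. With the number as a replicate block, 7650, 7539 and 4955 genes were called in the 3 pairwise comparisons. In simulated data at the observed depth and spread, but with few changed genes, edgeR found 1.5-fold changes in 0 of 35 genes under 5 CPM. It found 43.8% of those from 5 to 50 CPM and 92.9% of those above, and at 0.5 of the depth the percentages were the same. For 4-fold changes of genes under 5 CPM, recovery went from 81.1% to 73.0% at 0.5 of the depth.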

Other observations

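The other splits of the libraries were planned, and the tests of gene families, of Cdc20, of the shift between weakly and strongly expressed genes and of the vehicle libraries were chosen after the result was seen. Gene families were taken by symbol, and 7 were tested with camera in 3 comparisons (21 tests). Cytosolic ribosomal protein genes rose after PMA: 73 of 80 were higher and 2 lower (Rps27l and Rpl39l) at 6 h (51 and 3 without normalization), with a median log2 fold change of 0.87 (adjusted p = 4.4e-10; adjusted p = 0.341 with an estimated correlation). At 12 h 77 were higher and 0 lower (2 lower with upper-quartile scaling or without normalization, and at most 2 when 1 library was left out; median 0.92, adjusted p = 4.0e-11; adjusted p = 0.325 with an estimated correlation). Mitochondrial ribosomal protein genes fell, 55 of 67 at both times, with 0 higher at 6 h and 1 at 12 h (0 to 3 higher when 1 library was left out; medians -0.79 and -0.75, adjusted p = 3.1e-08 and 5.9e-08; adjusted p = 0.130 for both with an estimated correlation). In each of the 6 PMA libraries the mean level of the first family lay above, and that of the second below, all 3 vehicle libraries. With all genes ranked into 10 bins by their mean level over all 9 libraries, the highest bin had a median of 0.71 at 6 h. The rise of the first family stands close to that value, but genes that rose under PMA rank higher by this measure. All 9 claudin genes rose at 6 h (8 without normalization; median 2.45, adjusted p = 8.3e-04; adjusted p = 0.184 with an estimated correlation), higher in all 3 libraries than in vehicle, and Cldn4 reached 5998 CPM from 240 CPM in vehicle. Of 41 complex I genes 28 fell and 3 rose at 6 h (0 rose with upper-quartile scaling or without normalization; adjusted p = 0.00101; adjusted p = 0.278 with an estimated correlation). At 12 h 21 fell and 8 rose (2 and 0 rose under these scalings; 17 to 22 fell and 5 to 8 rose when 1 library was left out; adjusted p = 0.0382; adjusted p = 0.408 with an estimated correlation), and from 6 h to 12 h 15 rose and 2 fell (10 to 20 and 2 to 3 when 1 library was left out; adjusted p = 0.0322; adjusted p = 0.399 with an estimated correlation). Of 17 aminoacyl-tRNA synthetases 12 fell and 3 rose at 6 h (2 and 1 rose under these scalings; adjusted p = 0.0322; adjusted p = 0.325 with an estimated correlation). Of 14 Kruppel-like factors 8 rose and 0 fell at 6 h (2 and 4 fell under these scalings; adjusted p = 0.0176; adjusted p = 0.130 with an estimated correlation), and of 11 histone cluster genes 8 rose and 0 fell at 6 h (7 and 5 rose under these scalings; adjusted p = 0.0382; adjusted p = 0.184 with an estimated correlation). At 12 h the claudins had 8 higher (1 lower with upper-quartile scaling or without normalization, and at most 1 lower when 1 library was left out; adjusted p = 0.0055), the synthetases 12 lower and 2 higher (1 and 0 higher under these scalings, 1 to 3 higher when 1 library was left out; adjusted p = 0.0183), the Kruppel-like factors 11 higher and 2 lower (1 to 2 lower when 1 library was left out; adjusted p = 0.00347) and the histone cluster genes 9 higher (adjusted p = 0.0109), with adjusted p from 0.130 to 0.303 under an estimated correlation. From 6 h to 12 h none of the 7 families but complex I passed (adjusted p from 0.0513 to 0.794). The histone cluster genes were weakly expressed, with a mean log2 CPM of 0.49 to 0.62 in the vehicle libraries and 1.89 to 2.06 at 6 h.

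Single genes outside the lists, chosen after their values were seen, are given in CPM for vehicle, 6 h and 12 h. Ovol1 (6.74, 455 and 151) and Grhl3 (13.2, 562 and 168), transcription factors of epidermal differentiation, peaked at 6 h. Krt80 went from 54.9 to 405 and 657. Cmpk2 (0.860, 28.9 and 53.3), the chromosomal neighbour of Rsad2, rose with it, whereas the interferon-stimulated gene Isg15 stood at 5.42, 5.35 and 5.37.

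Cdc20 had 29.1, 58.0 and 121 CPM in the vehicle libraries, 727 to 822 CPM at 6 h and 650 to 801 CPM at 12 h, while the 20 other G2 and mitosis genes fell. It lies 244 bases from Elovl1 in a newer rat assembly, and under PMA its level was 33.4% to 40.8% of that of Elovl1. A fixed share of Elovl1 reads counted for Cdc20 is argued against by the vehicle libraries. That share would need 67.2 CPM there on average, and 2 of 3 libraries lay below it (29.1 and 58.0 CPM). A line through the 3 vehicle libraries put Cdc20 at -7.82 CPM (SE 6.78) at no other mitotic signal, but 3 points are too few for this fit to decide. Read-through of Elovl1 that itself rose under PMA cannot be told apart from a rise of Cdc20: its gain was 39.4% of that of Elovl1. Among 30 other adjacent pairs, counted once per gene that rose, the gain of the neighbour had a median of 0.0489% and a maximum of 144.5%. That maximum and the next value (69.2%) came from the same genes, Ppp1r15a and Nucb1, and the highest of the rest was 10.3%. Reads per exon would be needed, and a regulation of Cdc20 by PMA stays open and untested.

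The typical gene lost share of the counts under PMA, with a median log2 ratio of count shares to vehicle of -0.57 at 6 h and -0.60 at 12 h. The 100 most abundant genes took 28.2% of the counts at 6 h and 29.1% at 12 h against 23.4% in vehicle, but without them the shift was still -0.48 at 6 h, which argues against a few genes as its cause. The 6 h libraries had 1.01 times and the 12 h libraries 0.916 times the mean total of vehicle. Count shares are relative to each library total, so depth cancels out of them and this comparison was no separate test. Level, taken as the mean over all 9 libraries, had a rank correlation with the change at 6 h of 0.327 without those 100 genes. Over the same 10 bins the medians were -0.44 (lowest level), -0.80 (second lowest) and 0.71 (highest). Because 6 of the 9 libraries are PMA libraries, genes that rose also have a higher mean level. These values therefore cannot decide whether counts shifted broadly from weakly to strongly expressed genes. Without a spike-in the RNA per cell was not measured. Whether the lost share of the typical gene came from the cells or from the libraries stays open, and PMA is not separated from time in culture here either.

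In G2 and mitosis genes the level of vehicle replicate 1 was 23.8% of that of vehicle replicate 3 by the median. The difference was not confined to the cell cycle lists: of 7377 genes with a mean of at least 10 CPM in vehicle, 154 differed at least 2-fold between the vehicle libraries, 24 of them in the S phase and G2 and mitosis lists. At 6 h 15 of 6791 such genes differed so, and at 12 h 11 of 6797. Genes outside the lists were not sorted by function and can still belong to the cell cycle, such as Pbk (24.4 ± 12.2 CPM in vehicle). Ftl1, also outside the lists, stood at 5376, 3942 and 2626 CPM in vehicle replicates 1, 2 and 3. RNA of PMA-treated cells in vehicle replicate 1 would need to be 76.3% of that library, but the 29 genes at least 32-fold higher at 6 h than in vehicle replicates 2 and 3, chosen without vehicle replicate 1, stood there at a median of 1.26% of their 6 h level (at most 7.78%), which argues against it. Dividing fibroblasts in vehicle replicate 3 are argued against by their 13 markers, which summed to 25.6 CPM there, no higher than the 25.9 and 27.3 CPM in vehicle replicates 1 and 2. No other biological explanation was tested, since the labels name no difference between these libraries.

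Splitting the 6 libraries otherwise, the highest other count by edgeR was 0 at 6 h (real 7776) and 0 at 12 h (real 7682), and in each the real split is 1 of 10, too few for a share under 0.05. Over 100 drawn splits of the 9 libraries, the real split alone reached its value in 3 results (1 of 100 each, the smallest share possible here). They were genes changed over the 3 groups (8843, highest other 5896), genes changed the same way at both times (6202, highest other 5456) and the temporal classes (8293, highest other 5456). That is a share under 0.05 for the grouping as a whole. For the step from 6 h to 12 h within the classes, draws that keep the vehicle libraries together are too few to tell. The high counts of other splits point to the structure of the samples, since 3 drawn splits kept the vehicle libraries together, and with them apart the 3-group count was at most 514 and the overlap at most 0. For the 28 list calls chance is not excluded: 6 of 100 splits, the real one included, gave as many (highest other 31), and in the 5 others the vehicle libraries were apart.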
